A study of Rattus norvegicus with 6 samples.

How the data were processed

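Gene expression was measured on 6 rat Affymetrix arrays in RBL-2H3 cells, a rat basophilic leukaemia line widely used as a mast cell model, which stably expressed Dectin-1, a cell-surface receptor for beta-glucans. Per the labels, 2 arrays came from unstimulated control cells, 2 from cells stimulated with curdlan, a particulate beta-glucan, and 2 from cells given curdlan after R406, an inhibitor of the kinase Syk. The doses and the time of stimulation are not given in the sources used here. Total RNA was isolated with a column kit and labelled with biotin by a whole-transcript terminal labelling kit, per the labels' protocols.

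The deposited values are 1 log2 signal per probe set and array, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. The version of that program, its background correction, summarisation and between-array method, and the genome build are not given in the sources used here. The log base was inferred from the values: the highest signals lay between 14.37 and 14.41, which as log2 correspond to 21155 to 21772 on the linear scale of a scanner, whereas a natural logarithm would place them at 1738790 to 1812468. Array medians lay between 7.204 and 7.241, so the arrays had nearly the same distribution before any step taken here. A normalization of that kind removes any change shared by most transcripts. No detection call or background level was used here, so whether the changes of genes with low signals are understated is not known. For arrays, precision is limited by their number.

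The table held 29214 probe sets, and 0 columns belonged to other samples. The platform annotation gave 1 gene symbol for 15310 probe sets, several for 323 and none for 13581. The last are unnamed here and no gene was named from a probe set with several symbols. The named probe sets covered 14506 distinct genes, of which 527 had several probe sets. Control probe sets could not be recognised from the values and none was removed. Gene symbols, synonyms and the order of genes along the chromosomes came from a RefSeq table of the assembly GRCr8. No genome sequence was used here.

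All 6 arrays were fitted in 1 limma model with the 3 groups (R 4.3.3, limma 3.58.1, lmFit and eBayes), without filter or further normalization. It had 3 residual degrees of freedom, and empirical Bayes added 2.16 prior degrees of freedom with a prior standard deviation of 0.0656 log2 units. The contrasts were curdlan minus control, R406 plus curdlan minus curdlan, and R406 plus curdlan minus control. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 29214 probe sets. Errors of changes are standard errors from this model, with 2 arrays per group. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Arrays of 1 group correlated at 0.9975 to 0.9981 over probe sets, and arrays of different groups at 0.9939 to 0.9967. No pair of arrays was a duplicate: at most 39 of the 29214 values were identical between any 2 arrays.

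The groups, comparisons, alternatives, rule for named genes and 24 gene lists were fixed before the data were examined. The lists covered interleukins and haematopoietic growth factors, chemokines, immediate early genes, NF-kB targets and feedback, calcium, calcineurin and NFAT, MAP kinase feedback, Dectin-1 and ITAM signalling, JAK-STAT and SOCS, mast cell identity and granule, exocytosis machinery, eicosanoid synthesis, interferon-stimulated genes, pattern recognition and IL-1 family receptors, cell cycle, apoptosis regulators, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein and integrated stress response, heat shock, ribosomal proteins, reference genes, and markers of macrophages and neutrophils, of lymphocytes, and of fibroblasts and epithelia. Of their 506 entries, 458 were measured, each by the probe set with the highest mean signal of its gene. Lists were tested against the other genes with limma's camera, 2-sided, with a preset correlation of 0.01 and again with an estimated correlation (statmod 1.5.0), adjusted over the 24 lists. The estimated form uses the 3 residual degrees of freedom of the fit, so it is stricter also for lists with uncorrelated members. The test fry asked whether members moved on balance in 1 direction, without comparing them with other genes. Members were counted as called over all probe sets and also adjusted over the list alone.

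The rule for named genes took, for the curdlan and the R406 contrasts, the 12 raised and the 12 lowered genes with the largest change among those called whose arrays did not overlap, up to 4 called members of each list, and in every case Clec7a, Syk, Il3, Il4, Il13, Tnf, Ccl2, Nfkbiz, Nr4a1 and Egr1. Members of near-identical families, among them the Oas family, are uncertain because probes can be shared.

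The tests were first run on simulated data. With 200 of 29214 probe sets changed, in 20 simulations of the curdlan comparison, 50.9% of those changed 1.5-fold, 83.8% of those changed 2-fold and 96.3% of those changed 4-fold were called, with 5.24% false calls. In 50 simulations on 14506 genes, 100% of lists shifted by 0.5 log2 units were found and 3 of 950 unshifted lists were called. Probe sets varied independently in the simulations, so false calls of lists whose members vary together were not measured. Because the curdlan arrays enter both the curdlan and the R406 contrast, 20 simulations of unchanged groups sharing those arrays gave the correlation and covariance of the changes that shared arrays alone produce. They had almost no calls (0.15 and 0.05 on average), so they give no chance value for an overlap of calls. Alternatives tried were a replicate block, fits of only the 4 arrays of a contrast, each array left out in turn, quantile normalization, centring of arrays on their median, a filter on low signals, an intensity trend or robust setting in the variance model, 1 probe set per gene, and stricter thresholds. Splits of the arrays shared by a pair of contrasts were added after the results were seen. The labels name no batch, and none was tested. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.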

Results

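Transcript levels were compared between 3 groups of Dectin-1-expressing RBL-2H3 mast cells, with 2 arrays each: unstimulated control cells, cells stimulated with curdlan, and cells stimulated with curdlan after the Syk inhibitor R406. Values are log2 signals normalized by the authors, and changes are differences of group means with the standard error (SE) of the fit. The median signal of the 6 arrays lay between 7.204 and 7.241. Clec7a, the rat gene for Dectin-1 (probe set 10866019), had a mean signal of 7.07 in control, 7.22 in curdlan and 7.12 in R406 plus curdlan arrays, at the 48.8th percentile of all probe sets. Whether its probes detect the introduced receptor is not known here, since the species of the construct is not given in the sources used here. Its change with curdlan was 0.15 ± 0.0931 (limma, Benjamini-Hochberg adjusted p = 0.556). Syk (probe set 10797509) had a mean signal of 9.14 in control arrays, and its changes were -0.12 ± 0.0452 with curdlan (adjusted p = 0.31) and 0.07 ± 0.0452 with R406 (adjusted p = 0.446).

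The first comparison asked which transcripts respond to stimulation of Dectin-1. With curdlan, Il3 (probe set 10742668), which encodes a mast cell growth factor, rose by 4.12 ± 0.156 log2 units, a 17.4-fold change. The monocyte chemoattractant gene Ccl2 rose by 3.77 ± 0.0613, and the type 2 cytokine genes Il13 and Il4 rose by 3.15 ± 0.0675 and 2.26 ± 0.14. The orphan nuclear receptor genes Nr4a2 and Nr4a3 rose by 3.51 ± 0.0931 and 3.48 ± 0.096, and the transcription factor gene Egr3 by 3.23 ± 0.0702. In the other direction, Ddit4 (probe set 10832920), which encodes an inhibitor of mTORC1, fell by 3.47 ± 0.0911 and the pseudokinase gene Trib3 fell by 2.40 ± 0.0648. Other genes with large rises were Klrb1c at 2.70 ± 0.0836, Olr1 at 2.23 ± 0.119, Cish at 2.18 ± 0.0505, Nfkbiz at 1.79 ± 0.073 and Osm at 1.67 ± 0.0574. Klrb1c and Olr1, which encode C-type lectin-like receptors, had control signals of 5.62 and 5.52, well below the array medians. The remaining large falls were Ccng2 at -1.89 ± 0.0675, Chac1 at -1.77 ± 0.0728, Atf3 at -1.71 ± 0.135, Arl11 at -1.61 ± 0.0642, Inhbe at -1.38 ± 0.131, Adm at -1.27 ± 0.164, Cxcr4 at -1.17 ± 0.0863, Ddit3 at -1.12 ± 0.0747, Abhd18 at -1.12 ± 0.0545 and Gpr146 at -1.02 ± 0.0855. The adjusted p of these 24 genes lay between 0.000402 for Ccl2 and 0.0408 for Adm.

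**Figure D1:**
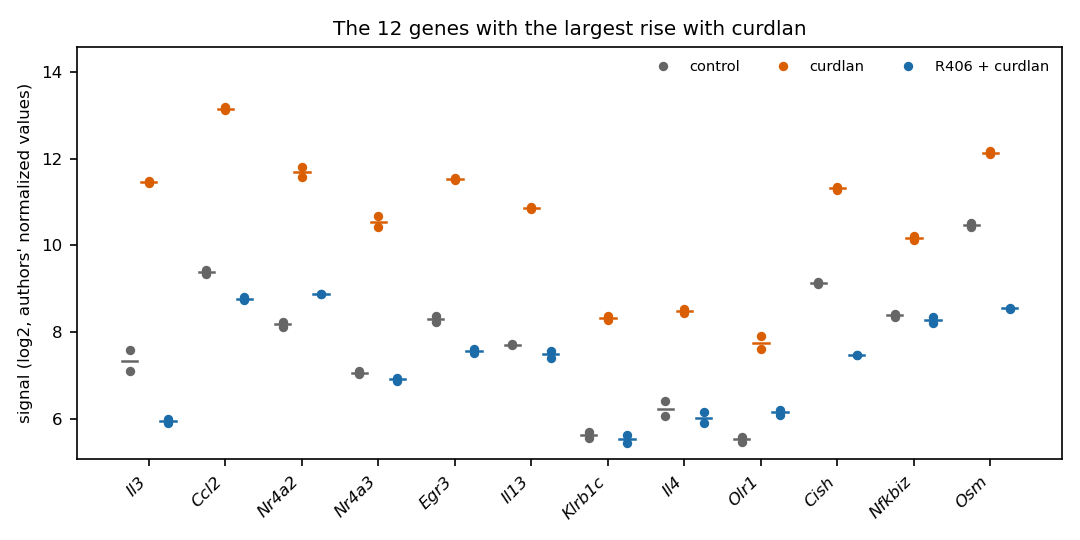
Signals (log2, authors' normalized values) of the 12 genes with the largest rise with curdlan, for control, curdlan and R406 plus curdlan arrays; each point is 1 array and each line the mean of 2 arrays. The mean signal of Il3 was 7.34 in control, 11.46 in curdlan and 5.95 in R406 plus curdlan arrays.

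Among 23 measured interleukin and growth factor genes, 7 rose and 0 fell (9 rose adjusted over the list alone), including Tnf at 1.40 ± 0.0763 besides Il3, Il13 and Il4. The list shifted upward against other genes (camera adjusted p = 2.69e-05, and adjusted p = 0.172 with an estimated correlation). Of 27 immediate early genes, 13 rose and 2 fell (16 and 2 adjusted over the list alone), with Ier3 at 1.41 ± 0.0548 and Egr1 at 0.90 ± 0.0792 among the risers and the stress-responsive factor Atf3 among those that fell. This list also shifted upward (camera adjusted p = 1.53e-14, and adjusted p = 0.0677 with an estimated correlation). Nr4a1, related to Nr4a2 and Nr4a3, had a change of -0.07 ± 0.12 (adjusted p = 0.851) and a control signal of 6.20. In the JAK-STAT and SOCS list 5 of 19 genes rose and 0 fell (6 and 3 adjusted over the list alone), led by the feedback inhibitor genes Cish and Socs1, the latter at 1.46 ± 0.0782, with Pim3 at 0.83 ± 0.0674 and Socs3 at 0.66 ± 0.0722 (camera adjusted p = 0.00315, and adjusted p = 0.196 with an estimated correlation). Of 17 NF-kB targets and feedback genes, 3 rose and 0 fell, also adjusted over the list alone: Nfkbiz, Nfkbia at 0.74 ± 0.044 and Icam1 at 0.57 ± 0.06. The NF-kB list had a camera adjusted p = 0.0277, and adjusted p = 0.26 with an estimated correlation. Its camera adjusted p was 0.0738 without control replicate 1, 0.0926 without control replicate 2 and 0.0906 without curdlan replicate 2, and 0.072 among probe sets above the median signal.

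Of 17 measured genes of the unfolded protein and integrated stress response, 0 rose and 7 fell with curdlan (9 fell adjusted over the list alone). They were Ddit4, Trib3, Chac1, Atf3, Ddit3, Herpud1 at -0.99 ± 0.0462 and Atf4 at -0.83 ± 0.0639. Atf4 and Ddit3 encode transcription factors of the integrated stress response, and Chac1 an enzyme that degrades glutathione. The list shifted downward (camera adjusted p = 2.59e-07, and adjusted p = 0.196 with an estimated correlation). In the glycolysis and hypoxia list of 20 genes, Pfkfb3 rose by 0.46 ± 0.0553 while Adm and Vegfa fell, the latter by 0.72 ± 0.0428 (1 rose and 3 fell adjusted over the list alone). That list shifted downward (camera adjusted p = 0.0277, and adjusted p = 0.71 with an estimated correlation), but its camera adjusted p was 0.0926 without control replicate 2, 0.184 without curdlan replicate 1 and 0.072 among probe sets above the median signal. The exocytosis machinery list of 20 genes had 0 called members (2 fell adjusted over the list alone) and a median change of -0.084 (camera adjusted p = 0.0179, and adjusted p = 0.243 with an estimated correlation). Its camera adjusted p was 0.0601 without control replicate 1.

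**Figure D2:**
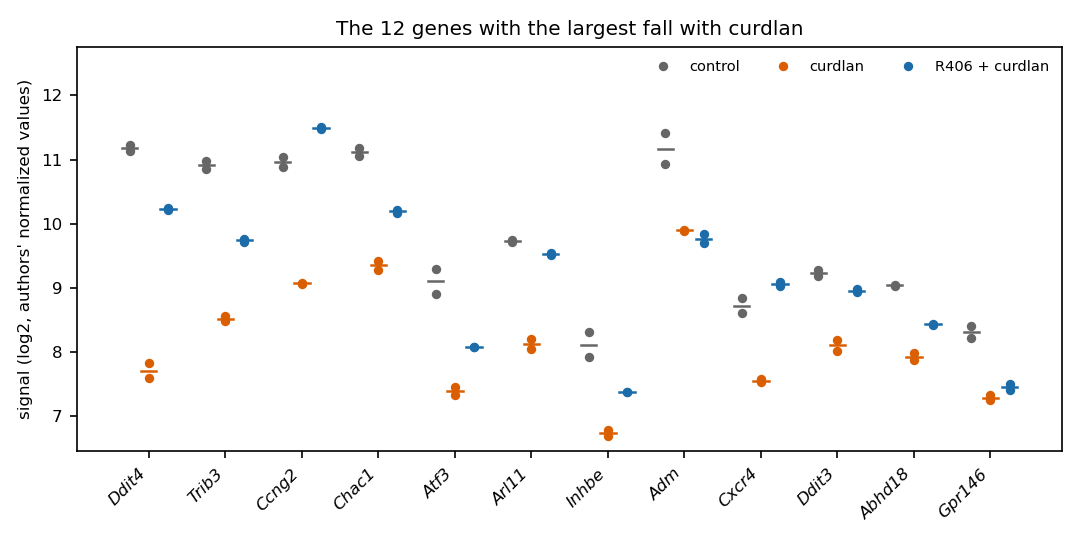
Signals (log2, authors' normalized values) of the 12 genes with the largest fall with curdlan, drawn as 1 point per array and 1 line per mean of 2 arrays for control, curdlan and R406 plus curdlan. The mean signal of Ddit4 was 11.18 in control, 7.71 in curdlan and 10.23 in R406 plus curdlan arrays.

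The MAP kinase feedback list went both ways with curdlan: the phosphatase genes Dusp5, Dusp7, Dusp6 and Dusp4 rose by 1.36 ± 0.0557, 0.82 ± 0.0542, 0.63 ± 0.0706 and 0.49 ± 0.0463, while Dusp1 fell by 0.99 ± 0.0685 and Dusp10 fell by 0.90 ± 0.0635. Of its 17 genes 4 rose and 2 fell (4 and 3 adjusted over the list alone), with a camera adjusted p = 0.967. Of 24 chemokine genes 2 rose, Ccl2 and Ccl7, the latter at 1.64 ± 0.0981 (3 rose adjusted over the list alone; camera adjusted p = 0.492). In the remaining lists, single genes rose: Tph1, which encodes a serotonin-synthesis enzyme, at 0.72 ± 0.0792 among 26 mast cell genes, Ptgs1 at 0.51 ± 0.0589 among 16 eicosanoid genes, and Ccne2 at 0.43 ± 0.048 among 23 cell cycle genes. Oasl, whose family shares sequence, and Irf1 rose by 0.52 ± 0.0687 and 0.51 ± 0.0716 among 23 interferon-stimulated genes. Gadd45b rose by 0.75 ± 0.0921 and Bcl2 fell by 0.42 ± 0.0558 among 22 apoptosis regulators. Adjusted over the list alone, 4 mast cell, 1 eicosanoid, 1 cell cycle and 2 interferon-stimulated genes rose, and 3 apoptosis regulators rose and 3 fell. The lists of calcium, calcineurin and NFAT, Dectin-1 and ITAM signalling, pattern recognition receptors, cholesterol synthesis, heat shock, ribosomal proteins, reference genes, macrophage and neutrophil markers, lymphocyte markers, and fibroblast and epithelial markers had 0 called members. Of these, the calcium list had 1 and the ITAM list 2 risers adjusted over the list alone. The 17 lists that did not pass had camera adjusted p between 0.414 and 0.967, and in 11 of them the median, mean and test differed in sign.

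In all, 465 of 29214 probe sets passed with curdlan (limma, Benjamini-Hochberg), 304 higher and 161 lower, covering 207 and 103 named genes. A change of at least 2-fold was seen in 54 of the raised and 14 of the lowered probe sets. The count was 59 without control replicate 1, 32 without control replicate 2, 50 without curdlan replicate 1, 44 without curdlan replicate 2, and 68 without R406 plus curdlan replicate 1 or 2, in fits with 2 residual degrees of freedom. Of 51 named genes called, 19 passed in each of these 6 fits: Il3, Ccl2, Nr4a2, Nr4a3, Egr3, Il13, Klrb1c, Cish, Nfkbiz, Osm, Ier3, Dusp5, Plk3, Ddit4, Trib3, Ccng2, Chac1, Arl11 and Herpud1.

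The second comparison asked how levels under R406 plus curdlan differ from those with curdlan alone. It cannot separate a blocked curdlan response from effects of R406 on unstimulated cells, or Syk from other kinases. Under R406, Il3 was lower than with curdlan alone by a 45.5-fold change, at -5.51 ± 0.156. Egr1 (probe set 10800919) fell by 4.68 ± 0.0792, Ccl2 fell by 4.39 ± 0.0613, and Dusp6, which encodes an ERK phosphatase, fell by 3.98 ± 0.0706. Egr3 fell by 3.97 ± 0.0702 and the proto-oncogene Myc fell by 3.93 ± 0.0807. The genes with the largest rise were Bcl6 (probe set 10751931), which encodes a transcriptional repressor, at 2.77 ± 0.0869, Ddit4 at 2.52 ± 0.0911, Ccng2 at 2.42 ± 0.0675 and Txnip, which encodes a thioredoxin inhibitor, at 2.15 ± 0.0538. Further falls were Cish at -3.85 ± 0.0505, Nr4a3 at -3.63 ± 0.096, Osm at -3.60 ± 0.0574, Il13 at -3.38 ± 0.0675, Plk3 at -3.31 ± 0.0438 and Ier3 at -3.30 ± 0.0548. Further rises were Ackr3 at 1.79 ± 0.116, Tcp11l2 at 1.63 ± 0.0595, Ypel3 at 1.60 ± 0.0485, Klhl24 at 1.52 ± 0.0824, Hbp1 at 1.44 ± 0.0609, Fbxl20 at 1.42 ± 0.0685 and Cx3cr1 at 1.41 ± 0.0894, and the chemokine receptor gene Cxcr4 rose 2.83-fold. A second, dimmer probe set of Fbxl20 had a change of 0.24 (adjusted p = 0.179). The adjusted p of these 24 genes lay between 6.09e-05 and 0.0031.

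Of 27 immediate early genes, 19 fell under R406 and 1, Atf3, rose by 0.68 ± 0.135 (19 and 2 adjusted over the list alone; camera adjusted p = 5.38e-16, and adjusted p = 0.0588 with an estimated correlation). Of 23 interleukin and growth factor genes 7 fell and 0 rose (8 fell adjusted over the list alone), among them Il4 at -2.47 ± 0.14 and Tnf at -2.70 ± 0.0763 (camera adjusted p = 3.21e-05, and adjusted p = 0.144 with an estimated correlation). In the MAP kinase feedback list 8 of 17 genes fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.000392, and adjusted p = 0.144 with an estimated correlation). Those that fell included Dusp5 at -2.93 ± 0.0557, Dusp4 at -2.52 ± 0.0463 and Spry4 at -1.79 ± 0.0513, while Dusp10 rose by 1.17 ± 0.0635. Of 24 chemokine genes 3 fell, Ccl2, Ccl7 at -1.59 ± 0.0981 and Cxcl10 at -0.58 ± 0.0658, also adjusted over the list alone (camera adjusted p = 0.0288, and adjusted p = 0.48 with an estimated correlation). The chemokine list had a camera adjusted p = 0.162 without curdlan replicate 1 and 0.0819 after quantile normalization. Of 17 NF-kB targets and feedback genes 5 fell and 1 rose, also adjusted over the list alone, with Nfkbiz at -1.90 ± 0.073, Ptgs2 at -1.41 ± 0.0547, Icam1 at -0.86 ± 0.06 and Birc3 at -0.79 ± 0.0648 (camera adjusted p = 0.0288, and adjusted p = 0.266 with an estimated correlation). Without curdlan replicate 2 the NF-kB list had a camera adjusted p = 0.0586. In the JAK-STAT and SOCS list 7 of 19 genes fell and 2 rose (7 and 3 adjusted over the list alone), with Socs1 at -3.24 ± 0.0782, Pim3 at -1.34 ± 0.0674 and Bcl6 on opposite sides, and the list did not pass (camera adjusted p = 0.0797).

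In the unfolded protein and integrated stress response list 8 of 17 genes rose under R406 and 0 fell, also adjusted over the list alone. They included Trib3 at 1.22 ± 0.0648, Atf4 at 1.03 ± 0.0639, Herpud1 at 0.88 ± 0.0462 and Ddit3 at 0.85 ± 0.0747 (camera adjusted p = 3.21e-05, and adjusted p = 0.219 with an estimated correlation). Of 20 exocytosis genes 6 rose and 0 fell (9 rose adjusted over the list alone), with Stxbp3 at 0.47 ± 0.0462, Syt11 at 0.40 ± 0.0773, Stx11 at 0.39 ± 0.0518 and Lyst at 0.38 ± 0.0728 (camera adjusted p = 0.000304, and adjusted p = 0.144 with an estimated correlation). Aurka and Plk1, which encode mitotic kinases, rose by 0.51 ± 0.0569 and 0.31 ± 0.0551 among 23 cell cycle genes (9 rose and 2 fell adjusted over the list alone). The cell cycle list shifted upward (camera adjusted p = 0.0155, and adjusted p = 0.48 with an estimated correlation), but had a camera adjusted p = 0.11 among probe sets above the median signal. Of 20 glycolysis and hypoxia genes 4 fell, also adjusted over the list alone: Hk2 at -0.93 ± 0.0645, Pfkfb3 at -0.86 ± 0.0553, Hif1a at -0.30 ± 0.0489 and Vegfa at -0.26 ± 0.0428. That list had a camera adjusted p = 0.0394, and adjusted p = 0.48 with an estimated correlation, with 0.137 without curdlan replicate 2, 0.0999 without R406 plus curdlan replicate 2 and 0.059 with arrays centred on their median. Hsph1 alone fell among 11 heat shock genes, at -0.24 ± 0.0457, also adjusted over the list alone. The heat shock list had a camera adjusted p = 0.0396, and adjusted p = 0.297 with an estimated correlation, and without each array in turn it did not pass, at 0.0532 without control replicate 1, 0.0533 without control replicate 2, 0.0571 and 0.111 without curdlan replicates 1 and 2, and 0.0587 and 0.103 without R406 plus curdlan replicates 1 and 2. With arrays centred on their median it had a camera adjusted p = 0.0687, and in the fit of 4 arrays 0.0533.

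**Figure D3:**
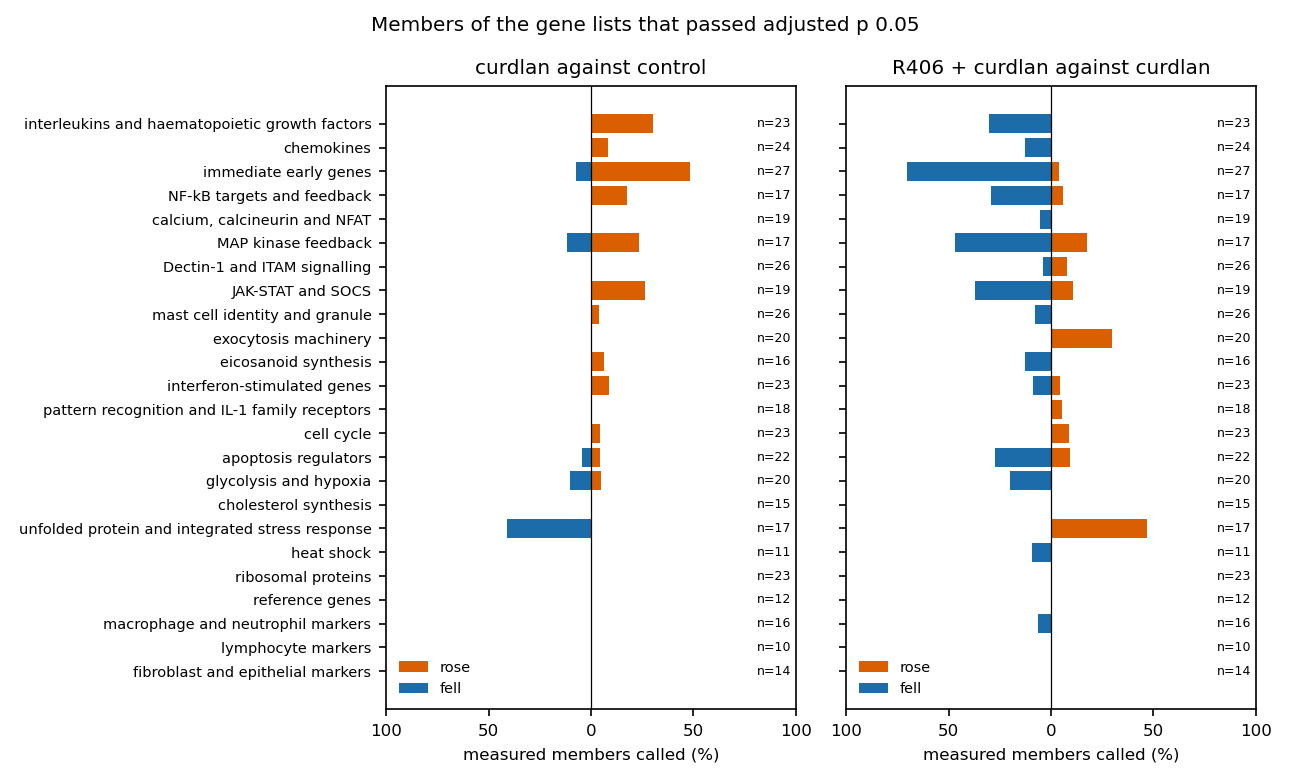
Share of the measured members of each gene list (percent, horizontal axis) that rose or fell at an adjusted p under 0.05, for curdlan against control and for R406 plus curdlan against curdlan; n is the number of measured members. Of 27 immediate early genes, 13 rose with curdlan and 19 fell under R406.

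In the lists that did not pass, Cd200r1, an inhibitory receptor gene, fell by 1.29 ± 0.0596 and Tph1 fell by 0.69 ± 0.0792 among 26 mast cell genes, and Ptgs2 and Ptgs1, the latter at -0.38 ± 0.0589, fell among 16 eicosanoid genes (3 fell adjusted over the list alone). Of 22 apoptosis regulators 6 fell and 2 rose (8 and 5 adjusted over the list alone), with Gadd45a at -1.25 ± 0.0487, Cdkn1a at -0.74 ± 0.0697 and Gadd45b at -0.60 ± 0.0921. Nfatc2 fell by 0.54 ± 0.0684 among 19 calcium, calcineurin and NFAT genes. Of 26 genes of Dectin-1 and ITAM signalling, Cblb and Sos1 rose by 0.32 ± 0.0521 and 0.22 ± 0.0425 and Ptpn6 fell by 0.26 ± 0.0464. Among 23 interferon-stimulated genes Oasl and Cxcl10 fell, the former by 0.69 ± 0.0687, and Stat2 rose by 0.32 ± 0.0465 (4 fell and 4 rose adjusted over the list alone). Irak3 rose by 0.36 ± 0.0543 among 18 pattern recognition genes, and Itgam fell by 0.36 ± 0.0661 among 16 macrophage and neutrophil markers. The counts of the mast cell, calcium, ITAM, pattern recognition and macrophage lists were equal adjusted over the list alone. The cholesterol synthesis, ribosomal protein, reference, lymphocyte, and fibroblast and epithelial lists had 0 called members, also adjusted over the list alone. The 14 lists that did not pass had camera adjusted p between 0.0797 and 0.945, and in 5 of them the median, mean and test differed in sign.

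In all, 2118 of 29214 probe sets passed under R406 (limma, Benjamini-Hochberg), 1173 higher and 945 lower than with curdlan alone, covering 756 and 586 named genes. A change of at least 2-fold was seen in 59 and 111 of them. The count was 1232 without control replicate 1 or 2, 532 and 599 without curdlan replicates 1 and 2, and 231 and 210 without R406 plus curdlan replicates 1 and 2. Most calls were lower without curdlan replicate 1 (210 higher and 322 lower) and without R406 plus curdlan replicates 1 (92 and 139) and 2 (81 and 129), as at a change of at least 2-fold and at an adjusted p under 0.01 (260 and 301). Of 79 named genes called, 50 passed in each of these 6 fits, among them Il3, Il4, Il13, Tnf, Ccl2, Egr1, Egr3, Myc, Dusp6, Bcl6, Ddit4, Ccng2, Txnip, Trib3 and Atf4.

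Of the 54 probe sets raised at least 2-fold by curdlan, 53 were called lower under R406, and of the 14 lowered at least 2-fold, 11 were called higher. The levels of Nr4a3, Il13, Il4 and Klrb1c under R406 differed from control by -0.15 ± 0.096, -0.23 ± 0.0675, -0.21 ± 0.14 and -0.09 ± 0.0836, none of them called. The control signals of Il4 and Klrb1c, 6.23 and 5.62, lay well below the array medians. Whether a fall below control could be seen for these genes is not known, since no background level was used. Ddit4 and Trib3, lowered by curdlan, stayed below control at -0.95 ± 0.0911 and -1.18 ± 0.0648, and Nr4a2 stayed above it at 0.70 ± 0.0931. Adm and Gpr146 showed no called change with R406, at -0.13 ± 0.164 and 0.17 ± 0.0855 (adjusted p = 0.713 and 0.325). Over all sizes, 242 of the 304 raised probe sets (79.6%) were called lower under R406, where independent lists would share 9.83, and 105 of the 161 lowered ones (65.2%) were called higher, where independent lists would share 6.46. Across probe sets, which are not independent, the correlation of the curdlan and R406 changes was -0.591 against -0.501 in simulated unchanged groups that share the curdlan arrays, and the covariance was -0.0274 against a simulated -0.00531. Next, curdlan replicate 1 was used for the curdlan changes and curdlan replicate 2 for the R406 changes, so that no array entered both changes. The correlation was then -0.456 and the covariance -0.0231, and with the arrays exchanged they were -0.248 and -0.0148. The calls were less separate, because in these splits both fits took their error from the same control and R406 plus curdlan arrays. Independent lists are therefore no chance value for an overlap of these calls. The same holds for the full fit, whose contrasts share 1 error estimate per probe set. In the first of these splits 32 of 32 raised and 9 of 12 lowered probe sets were called in the opposite direction under R406, where independent lists would share 0.353 and 0.0863, and in the second 38 of 41 and 8 of 9, where they would share 0.386 and 0.0998. The overlap of raised probe sets was 44 and 23 without control replicates 1 and 2, 40 and 32 without curdlan replicates 1 and 2, and 47 and 46 without R406 plus curdlan replicates 1 and 2. The overlap of lowered ones was 12, 8, 7, 11, 7 and 7 in the same order.

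**Figure D4:**
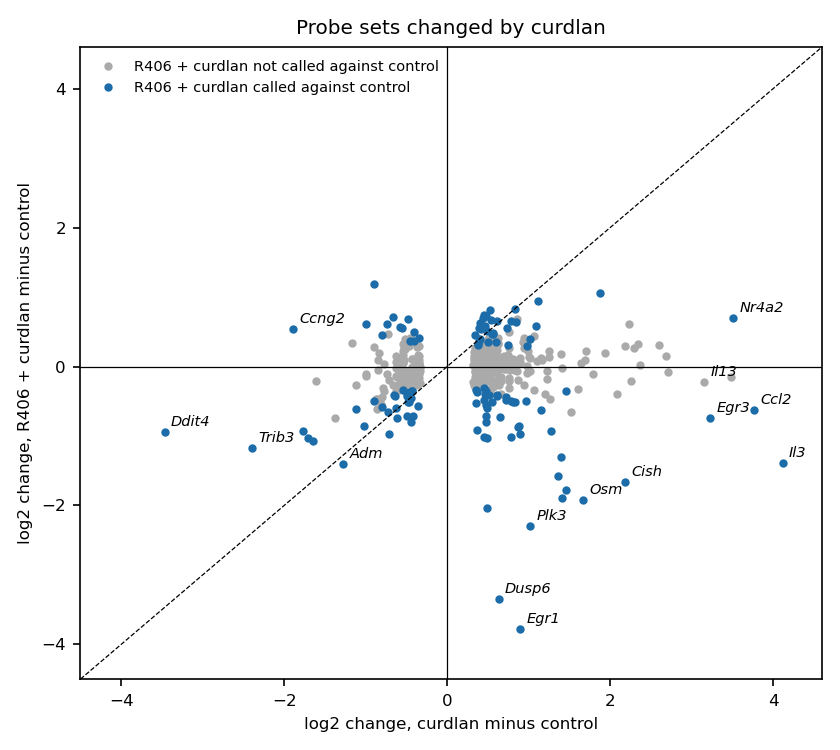
Log2 change from control under R406 plus curdlan (vertical axis) against the log2 change with curdlan (horizontal axis) for the 465 probe sets changed by curdlan; points on the dashed line have equal changes and blue points were called against control under R406. Il3 lay at 4.12 with curdlan and at -1.39 under R406.

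The third comparison set R406 plus curdlan against unstimulated control. Egr1 and Myc lay below control at -3.78 ± 0.0792 and -3.38 ± 0.0807, although Myc had not passed with curdlan (0.55 ± 0.0807, adjusted p = 0.0537). The ERK feedback genes Dusp6, Dusp4, Spry4 and Dusp5 were lower at -3.34 ± 0.0706, -2.03 ± 0.0463, -1.70 ± 0.0513 and -1.57 ± 0.0557. Plk3, Osm, Ier3, Socs1 and Cish were lower at -2.30 ± 0.0438, -1.93 ± 0.0574, -1.89 ± 0.0548, -1.77 ± 0.0782 and -1.67 ± 0.0505, and Il3, Ptgs2 and Tnf at -1.39 ± 0.156, -1.37 ± 0.0547 and -1.30 ± 0.0763. Bcl6, Txnip, Tcp11l2 and Ypel3 lay above control at 2.18 ± 0.0869, 1.92 ± 0.0538, 1.80 ± 0.0595 and 1.52 ± 0.0485. Their adjusted p lay between 0.000513 and 0.0263. Of 17 MAP kinase feedback genes 7 were lower and 0 higher (8 and 2 adjusted over the list alone; camera adjusted p = 1.69e-05, and adjusted p = 0.174 with an estimated correlation). Of 27 immediate early genes 10 were lower and 2 higher (17 and 2 adjusted over the list alone; camera adjusted p = 6.6e-09, and adjusted p = 0.139 with an estimated correlation). Of 23 interleukin and growth factor genes 5 were lower, also adjusted over the list alone (camera adjusted p = 0.00732, and adjusted p = 0.315 with an estimated correlation). Hk2, Pfkfb3, Vegfa and Adm were lower among 20 glycolysis and hypoxia genes, at -1.11 ± 0.0645, -0.40 ± 0.0553, -0.98 ± 0.0428 and -1.40 ± 0.164 (6 adjusted over the list alone; camera adjusted p = 1.09e-05, and adjusted p = 0.325 with an estimated correlation). Aurka was higher at 0.56 ± 0.0569 among 23 cell cycle genes (6 adjusted over the list alone; camera adjusted p = 0.00187, and adjusted p = 0.449 with an estimated correlation). The cholesterol synthesis list of 15 genes, with 1 lower member (2 adjusted over the list alone), shifted downward (camera adjusted p = 0.0348, and adjusted p = 0.325 with an estimated correlation). Its camera adjusted p lay over 0.05 in 5 of the 6 fits with 1 array left out, at 0.0769 without control replicate 1, 0.0584 and 0.0583 without curdlan replicates 1 and 2, and 0.0635 and 0.0637 without R406 plus curdlan replicates 1 and 2, and was 0.0593 with arrays centred on their median and 0.0584 in the fit of 4 arrays.

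Of the 18 lists that did not pass against control, the JAK-STAT and SOCS list had 5 lower and 1 higher of 19, the stress response list 4 lower of 17, apoptosis regulators 4 lower and 1 higher of 22, and NF-kB targets 2 lower and 2 higher of 17. Chemokines had 2 lower of 24, exocytosis machinery 2 higher of 20, calcium, calcineurin and NFAT 1 lower and 1 higher of 19, Dectin-1 and ITAM signalling 1 higher of 26, mast cell genes 1 lower of 26, and eicosanoid synthesis 1 lower of 16. The interferon-stimulated, pattern recognition, heat shock, ribosomal protein, reference, macrophage and neutrophil, lymphocyte, and fibroblast and epithelial lists had 0 called. Adjusted over the list alone, the lower and higher genes numbered 7 and 5 for JAK-STAT, 6 and 0 for the stress response, 6 and 1 for apoptosis, 4 and 2 for NF-kB, 3 and 1 for chemokines, 0 and 4 for exocytosis, 1 and 2 for calcium, 1 and 2 for ITAM signalling, 1 and 1 for mast cell genes, 1 and 0 for eicosanoids, 0 and 2 for pattern recognition, 2 and 0 for heat shock, and 0 in the others. Camera adjusted p of these lists lay between 0.0793 and 0.936, and in 5 of them the median, mean and test differed in sign. In all, 652 probe sets differed from control, 421 higher and 231 lower (limma, Benjamini-Hochberg). The count was 17 without control replicate 1 or 2, 182 without curdlan replicate 1 or 2, and 19 and 15 without R406 plus curdlan replicates 1 and 2. Most of these few calls were lower without control replicates 1 (5 higher and 12 lower) and 2 (4 and 13) and without R406 plus curdlan replicates 1 (7 and 12) and 2 (4 and 11), and at a change of at least 2-fold 26 were higher and 28 lower, and at an adjusted p under 0.01 30 and 36. Of 48 named genes called, 14 passed in each of these fits: Egr1, Myc, Dusp6, Dusp4, Dusp5, Spry4, Plk3, Osm, Ier3, Cish, Bcl6, Txnip, Tcp11l2 and Ypel3.

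The 304 curdlan-raised probe sets were split by their level under R406: 227 were not called against control, 32 were called above it and 45 below it, where independent lists would share 4.38 above and 2.4 below. Of the 161 curdlan-lowered probe sets 117 were not called, 31 were below control and 13 above it, where independent lists would share 1.27 and 2.32. These comparisons share the control arrays, which alone gave a simulated correlation of 0.504 and covariance of 0.00534, against 0.227 and 0.00872 observed. With the control arrays split between them, the correlation was -0.0162 or 0.0623 and the covariance -0.000768 or 0.00277. Both fits of such a split took their error from the same curdlan and R406 plus curdlan arrays. Their calls are therefore not independent, and independent lists are no chance value for an overlap. In these splits, which called few probe sets, 0 were called on the curdlan side of control, and 6 of 23 or 7 of 46 raised ones were called below control, where independent lists would share 0.00945 or 0.0205. The median share of the curdlan change left under R406 was 4.87% over the raised probe sets (SD 1.54 over 4 pairs of arrays) and 22.9% over the lowered ones (SD 2.78). The pairs combined curdlan and R406 arrays, with the control mean and the chosen probe sets held fixed. These SDs therefore leave out the spread of the control arrays and the choice of probe sets. They also do not describe the spread over probe sets. The quartiles of the share were -33.1% and 34.7% over raised probe sets and -16.5% and 56.3% over lowered ones. Both median shares differed between settings: without control replicate 2 they were -23.3% and 50.4%, and over probe sets changed at least 2-fold they were -2.08% and 50.8%. Of the 1173 probe sets raised by R406, 1067 had not been called with curdlan, and 314 of these were also above control. Of the 945 lowered by R406, 700 had not been called with curdlan, and 124 of these were also below control. Not called does not mean unchanged, since the smallest called change was 0.32 with curdlan and 0.219 under R406. Bcl6, for example, had a change of -0.59 ± 0.0869 with curdlan (limma adjusted p = 0.0537). No array of cells given R406 without curdlan was analysed here.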

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

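The alternatives were chosen before the data were examined, except the block with crossed control numbers and the splits of shared arrays, chosen after results were seen. No named gene reversed direction with a call in any setting, and quantile normalization, median centring and the robust variance model kept the counts of changed probe sets within 1.5 times. The labels number the arrays 1 and 2, and whether the numbers pair them is not known. Deviations of same-numbered arrays correlated at -0.115 between control and curdlan and -0.005 between control and R406 plus curdlan. Between curdlan and R406 plus curdlan they correlated at 0.113. These values show no strong shared deviation over probe sets, but with 1 difference per group they cannot exclude pairing. With the replicate block, 102, 1129 and 62 probe sets passed for curdlan, R406 and R406 plus curdlan against control (465, 2118 and 652 without), with overlaps of 74 raised and 18 lowered and a median share left of -1.85% over raised probe sets, and 38.7% of the calls against control were higher, compared with 64.6%; the glycolysis and hypoxia list lost its call for R406 (camera adjusted p = 0.0512). With crossed control numbers the curdlan count was 140. Fits of the 4 arrays of a contrast gave 68, 1232 and 182, overlaps of 53 and 10, and shares of -5.06% and 38.2%. An array left out gave 32 to 68, 210 to 1232 and 15 to 182 probe sets, overlaps of 23 to 47 and 7 to 12, shares of -23.3% to -3.12% and 24.8% to 50.4%, and 5 to 7, 7 to 9 and 5 to 7 lists. The lone array of a group was assumed to vary like the other groups. These fits have 2 residual degrees of freedom in place of 3, which lowers the counts by construction.

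Probe sets above the median signal gave 1572, 3717 and 2278, overlaps of 641 and 506, and a share of 4.57% over lowered ones, and the intensity trend gave 1557, 3767 and 2341, overlaps of 654 and 436, and 10.8%. The use of 1 probe set per gene gave 1064 against control, an overlap of 189 lowered, and shares of 3.12% and 8.84%. At least 2-fold changes gave 68, 170 and 54, overlaps of 47 and 6, and shares of -2.08% and 50.8%. An adjusted p under 0.01 gave 78, 561 and 66, overlaps of 60 and 11, and shares of -5.06% and 25.8%. Shares were -1.61% and 26.1% after quantile normalization and 6.999% and 14.7% after median centring. Probe sets were also chosen by a change of at least 2-fold on 1 curdlan array, without an adjusted p, and measured on the other. The share over raised ones was 3.598% and 10.9%, and over lowered ones 49.99% and 51.4%. Because of the 2-fold limit, these compare with the -2.08% and 50.8% above and not with the main shares. Measured on the array used for choosing, the shares were 6.54% and 12% over raised ones and 12.2% and 44.5% over lowered ones. Choosing and measuring on the same array thus gave lower shares over lowered probe sets, and no lower shares over raised ones. With 1 curdlan array for each contrast, overlaps were 32 and 38 raised and 9 and 8 lowered. The cause of the other differences between settings was not tested, except that the threshold settings select fewer probe sets by construction. With an estimated correlation 0, 0 and 0 of the 24 lists passed, against 7, 10 and 6 with the preset value. Correlated members do not account for all of this loss. The estimate was -0.0205 for immediate early genes, -0.012 for interleukins and -0.0269 for MAP kinase feedback, below the preset 0.01. It lay above 0.01 for the chemokine, cell cycle, glycolysis and stress response lists, at 0.172, 0.203, 0.14 and 0.0809. The estimated form also uses fewer degrees of freedom. The test fry called 9, 15 and 13. Probe sets passing an unadjusted p under 0.05 numbered 4214, 6440 and 5953. What signal over background limits was not analysed here, since no background level was used.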

Other observations

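The tests of R406 without curdlan, shared curdlan arrays and chaperone genes were chosen after the results were seen, and the FOXO, ribosome biogenesis and neighbour tests were written before their results, on ideas that arose from the genes with the largest changes, and the p-values of the FOXO and ribosome biogenesis lists are adjusted over these 2 lists.

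Nucleolar genes of ribosome biogenesis, a process that MYC is known to promote, were lower under R406. Of 18 such genes, in a list made after Myc was seen among the largest falls, 9 fell and 0 rose against curdlan (13 fell adjusted over the list alone), with Rrs1 at -0.97 ± 0.0813, Polr1b at -0.81 ± 0.0512, Wdr43 at -0.74 ± 0.0478 and Gnl3 at -0.48 ± 0.0466. The median change was -0.246 and 1 of 18 lay above 0 (camera adjusted p = 3.5e-10, and adjusted p = 0.0124 with an estimated correlation). Against control 3 fell, with a median of -0.171 (camera adjusted p = 4.31e-08, and adjusted p = 0.0179 with an estimated correlation). With curdlan 0 were called and the median was 0.042 (camera adjusted p = 0.000382, and adjusted p = 0.0547 with an estimated correlation). The list passed in each of the 3 comparisons with any 1 array left out. A candidate explanation is that these genes follow Myc, which the test could have contradicted but cannot separate from other effects of the inhibitor. The ribosomal protein list had 0 called members.

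Bcl6, Ccng2 and Txnip, picked from the largest rises under R406, are described targets of FOXO transcription factors, which kinase signalling through AKT holds inactive. Gadd45a and Cdkn1a, also described targets but in neither group, went the other way against curdlan, at -1.25 ± 0.0487 and -0.74 ± 0.0697. Against control Gadd45a was lower at -1.03 ± 0.0487, and Cdkn1a was not called (-0.31 ± 0.0697). A list of 18 other FOXO targets and FOXO genes, whose values had not been looked at, lay above control under R406 with a median of 0.212, with 14 of 18 above 0 (camera adjusted p = 1.25e-05, and adjusted p = 0.0179 with an estimated correlation). Of these, 3 were called higher, Fbxo32 at 0.68 ± 0.0928, Ulk1 at 0.65 ± 0.0468 and Gabarapl1 at 0.39 ± 0.0465, and 0 lower (9 higher adjusted over the list alone). Against curdlan 6 rose and 1, Foxo1, fell (camera adjusted p = 0.00628, and adjusted p = 0.0597 with an estimated correlation). With curdlan the list did not pass (camera adjusted p = 0.261), and with any 1 array left out it passed in both R406 comparisons. Higher FOXO activity may be one part of the response, as a hypothesis found and tested on the same arrays. The falls of Gadd45a, Cdkn1a and Foxo1 against curdlan go against it.

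Under R406, 231 probe sets lay below unstimulated control, with a median of -0.494, among them Egr1, Myc and Dusp6. With arrays centred on their median, 189 probe sets lay below control. Signalling that R406 blocks may already be active in unstimulated cells, and this cannot be told apart from effects of the inhibitor on other kinases, because 0 arrays of cells given R406 without curdlan were analysed here.

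Stress response genes that fell with curdlan rose again under R406, and 2 technical or biological explanations were weighed. Chance values of the shared curdlan arrays are argued against: 8 list members fell by over 0.5 on curdlan replicate 1, and their rise under R406 measured against curdlan replicate 2 had a median of 0.828, with 8 of 8 rising, while with the arrays exchanged 7 of 7 rose with a median of 0.931. Transcripts of 6 endoplasmic reticulum chaperones, Hspa5, Hsp90b1, Calr, Pdia4, Sdf2l1 and Creld2, showed little change with curdlan. Their median change was 0.001, between -0.056 and 0.022, against -1.706 for the 7 members that fell, which were selected for falling. A lower load on the endoplasmic reticulum is not excluded by this. The chaperones were chosen after the results were seen, transcripts do not measure the load, and Herpud1 of the same list fell, at -0.99 ± 0.0462. A biological effect of Dectin-1 signalling on ATF4 targets stays open, as untested.

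Several curdlan-raised genes lie next to each other on a chromosome, and whether that exceeds chance was tested. Of 206 raised genes placed among 14481 genes of the array in the order of GRCr8, 7 pairs were neighbours, including Il4 with Il13, Ccl2 with Ccl7, Osm with Lif and Klrb1c with Klrb1; Lif and Klrb1 were named after their values were seen. Random draws of genes matched on mean signal gave 3.45 pairs on average and 13 at most in 10000 draws (permutation p = 0.06, 1-sided), so chance placement is not excluded. With pairs of the same symbol start left out, 5 remained against 3.36 (permutation p = 0.2). Il4 with Il13 counted as different starts and stayed, so this filter does not remove every pair of related genes. Probes shared between paralogs cannot be told apart from chance here because no excess was established.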
